A study of Gallus gallus with 18 samples.

How the data were processed

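Poly(A) RNA was sequenced from LMH cells, a chicken hepatoma line from a Leghorn male, that had been infected with fowl adenovirus serotype 4 at a multiplicity of infection of 5 or mock infected. Harvests at 3 times (12, 24 and 48 h) make 6 groups with 3 biological replicates each and 18 libraries. The 18 count columns hold counts per gene, and per the file headers the unit is raw counts. The 18 FPKM columns hold FPKM values, as deposited by the authors. For genes with over 50 counts, the deposited FPKM followed from the counts and each column's own count total within a relative deviation of 1e-05. The FPKM columns were not used for any test, and 0 value columns were left unassigned. The submitters' processing notes name CASAVA 1.8, HISAT2 2.0.4, StringTie 1.3.0 and edgeR, without roles and without a version for edgeR. The genome build and the annotation version are not given in the sources used here.

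The columns are named DZ or JD with a time and a replicate number. DZ was read as the initials of duizhao, the Chinese word for control, and was taken as mock; JD was read as those of jiedu, inoculation with virus, and was taken as infected. This reading rests on the names and not on the values, and the direction of every difference between infected and mock cells rests on it.

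The table lists 24881 genes with Ensembl identifiers, of which 12471 carry a symbol and 12410 do not. Genes without a symbol were tested but are not named, because the reference table used here pairs no Ensembl identifiers with symbols. Genes were kept when they passed edgeR's filter by expression over the 6 groups (minimum count 10, minimum total 15), which left 14235 genes for testing, 4604 of them without a symbol, and left out 10646. Viral transcripts are not among the genes of this table and were not analysed here, and no spike-in was used, so that every change is relative to the pool of host mRNA.

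Counts were scaled with TMM factors and fitted in R 4.3.3 with edgeR 4.0.16, in 1 quasi-likelihood model over the 18 libraries with 12 residual degrees of freedom. The common biological coefficient of variation was 9.45%. Adjusted p-values of genes come from edgeR's quasi-likelihood F-test, two-sided, with the Benjamini-Hochberg correction over all genes tested, and a gene is said to have risen, fallen or changed when this value is under 0.05. The comparisons were infected against mock cells at each time, the average of these 3 differences, the difference between the infection effects at 12 and 24 h and at 24 and 48 h, and a joint test of the 3 mock groups. Standard errors are the absolute log2 fold change divided by the square root of F. They therefore belong to each test and do not add up from 1 comparison to the next. Levels are mean CPM after TMM scaling, with the SD over 3 replicates. For a gene with 0 counts in all 3 libraries of a group, the fold change is given as a lower bound from a floor of 3 counts over the group. The fitted value is no bound. Floors cover counting error only.

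Gene lists were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation between genes of 0.01, against all other tested genes, with the Benjamini-Hochberg correction over 26 lists and 3 times together. The same test with an estimated correlation, and fry, which tests whether the members move on balance in 1 direction and makes no comparison with other genes, were run beside it. The 27 lists cover innate immunity, cell cycle, liver function, lipid synthesis, stress responses, cell death, matrix, energy metabolism, virus entry and nuclear transport, gene expression machinery, reference genes and markers of other lineages. The list of mitochondrially encoded genes had fewer than 3 tested members and was not tested as a list. KEGG pathways and GO terms came from the deposited table, which annotates 2595 and 8607 of the tested genes, and terms with 15 to 300 tested members were tested in the same way over the 3 times together.

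The lists, the tests, the alternatives and the rule for naming genes were fixed before the data were examined, apart from some tests and 1 alternative. These exceptions were chosen after a result was seen and are named as such below. At each time the rule takes the 5 genes with the largest rise and the 5 with the largest fall among genes with a symbol, an adjusted p under 0.05, no overlap between the 3 infected and 3 mock values, at least 1 CPM in the higher group and more than 3 counts in the lower. It adds up to 3 members of each list that passed its test and 1 of each other list, by smallest adjusted p. It also adds CXADR, IL8L2 (IL8), MX1, MYC, MDM2 and ALB, and 3 genes per direction for each difference between times and for the mock time course. CXADR, IL8L2 and MX1 were not among the tested symbols. Genes that the rule does not take are named only where the text says so. Some genes that it takes are not reported here.

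Libraries held 2.12 to 14.3 M counts, and 3 counts correspond to 0.210 CPM in the deepest and 1.42 CPM in the shallowest. The test was run on simulated data, in which 200 genes were changed by 1.5-, 2- or 4-fold. At 48 h it recovered 56.9% of the 1.5-fold, 79.1% of the 2-fold and 92.3% of the 4-fold changes, with 3.23% false calls. For the difference between 12 and 24 h it recovered 25.0%, 66.2% and 86.2%, with 5.74% false calls. In the simulation all other genes were unchanged, whereas 73.4% of tested genes changed at 48 h in the data. These rates may therefore not carry over to the real comparisons.

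Each count of genes was recomputed with DESeq2 size factors, upper quartile scaling, library totals alone, scaling on reference genes, other filters on low counts, DESeq2 1.42.0, limma-voom, a fit of the compared groups alone, a test for changes beyond 1.5-fold, and each of the 18 libraries left out in turn. The counts were also set against other splits of the same samples. Genes called silent had less than 0.1 CPM in the pooled mock libraries; those that gained had at least 1 CPM over the pooled infected libraries at 48 h and counts in all 3, and an active neighbour had at least 10 CPM in mock cells.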

Results

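Host mRNA of LMH cells was counted gene by gene at 12, 24 and 48 h after infection with fowl adenovirus serotype 4, or after mock infection, in 3 replicates of each of the 6 groups. Mock libraries held 12.2 ± 2.59 M counts at 12 h (mean and SD, n = 3), 12.9 ± 0.237 M at 24 h and 12.3 ± 0.630 M at 48 h. Infected libraries held 9.22 ± 0.223 M at 12 h, 6.56 ± 0.363 M at 24 h and 2.38 ± 0.347 M at 48 h, so that the counts of host genes in a library were lowest where infection had lasted longest. The first principal component of log2 CPM, with 71.3% of the variance, ordered the groups from mock cells through 12 and 24 h to 48 h of infection.

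At 12 h, the question was which host genes differed early in infection. Adjusted p-values of genes here and below are from edgeR's quasi-likelihood test with the Benjamini-Hochberg correction, and those of lists from camera; the build of the coordinates is not given in the sources used here. Genes of DNA replication rose, as did genes of the amino acid response, and genes of the differentiated liver cell fell. TYMS, the thymidylate synthase that supplies a DNA precursor, rose from 79.9 ± 2.98 to 232 ± 2.76 CPM (SD, n = 3), a log2 fold change of 1.54 ± 0.062 (SE, adjusted p = 3.46e-13). CHAC1, a glutathione-degrading enzyme induced by the transcription factor ATF4, rose from 7.44 ± 0.732 to 96.5 ± 14.2 CPM, a log2 fold change of 3.69 ± 0.15 (adjusted p = 3.66e-13). G6PC, the glucose-6-phosphatase that releases glucose from liver cells, fell from 231 ± 13.7 to 83.4 ± 7.30 CPM, a log2 fold change of -1.47 ± 0.095 (adjusted p = 2.84e-10).

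Of 39 measured genes of S phase and DNA replication, 36 rose and 0 fell, in the same number adjusted over the list alone, with a median log2 fold change of 0.88 (list adjusted p = 1.36e-22). DTL, an adaptor of a ubiquitin ligase that acts at replication forks, rose by 1.95 on the log2 scale and GINS2, a subunit of the replicative helicase, by 2.46. Of 24 genes of the ATF4 and amino acid response, 18 rose and 1 fell, and 18 and 1 did adjusted over the list alone (median 0.69, adjusted p = 9.74e-10). MTHFD2, a mitochondrial enzyme of folate metabolism, rose by 2.55 and ASNS, asparagine synthetase, by 1.67. Proteasome subunits rose in 12 of 26 cases with 0 falls, and in 12 adjusted over the list alone (median 0.10, adjusted p = 0.0343). Among them were PSMD10, PSMD2 and PSMC5, at 0.80, 0.40 and 0.46. The call of this list was lost without replicate 3 of mock cells at 12 h (adjusted p = 0.0835), without replicate 1 of infected cells at 12 h (0.0715), and with an adjusted p = 0.770 with an estimated correlation.

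Of 33 hepatocyte secreted proteins, 28 fell and 0 rose, and 29 fell adjusted over the list alone (median -0.95, adjusted p = 7.08e-13). APOB, the main protein of very-low-density lipoprotein, had a log2 fold change of -1.97 ± 0.27 (adjusted p = 4.26e-06), and FGA, FETUB and F13B, which encode a fibrinogen chain, fetuin B and a subunit of coagulation factor XIII, had -1.15, -1.22 and -0.86. Of 26 liver transcription factors and metabolic enzymes, 24 fell and 1 rose, and 24 and 1 did adjusted over the list alone (median -0.81, adjusted p = 5.46e-08). HNF4A, a transcription factor of liver genes, had -1.17 and G6PC -1.47. Members of these lists rose in mock cells between 12 and 48 h, by a median of 0.52 over both lists. Of 32 listed interferon-stimulated genes, 18 were tested. Of these 18, 11 fell and 0 rose, and 13 fell adjusted over the list alone (median -0.42, adjusted p = 0.00333). TRIM25, a ubiquitin ligase of the RIG-I pathway, had -0.66 ± 0.11, PARP12 had -0.56 and CD47, a cell surface protein, -0.48. Of 66 ribosomal proteins, 21 fell and 1 rose, and 18 fell and 1 rose adjusted over the list alone (median -0.20, adjusted p = 0.00155), with RPL21, RPS24 and RPL12 at -0.49, -0.42 and -0.30. This call was lost without replicate 2 of infected cells at 12 h (adjusted p = 0.0603), and had an adjusted p = 0.876 with an estimated correlation. The other 5 lists called at 12 h apart from proteasome subunits and ribosomal proteins kept their call with an estimated correlation.

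Among genes with a symbol, more than 3 counts in the lower group and no overlap between groups, the largest rises at 12 h were those of OSTN, MMEL1, NCF4, MKX and HEPACAM, with log2 fold changes of 4.74, 4.55, 4.50, 4.46 and 4.37. OSTN (ENSGALG00000007226, chromosome 9, 13761297 to 13772476), which encodes the secreted peptide osteocrin, went from 0.160 ± 0.114 to 4.85 ± 0.578 CPM (adjusted p = 3.17e-10). By the same rule the largest falls were those of SP9, FAM135B, cFuc-TIX, APOB and NSUN7, of which SP9, a transcription factor, went from 1.75 ± 0.286 to 0.139 ± 0.0611 CPM (log2 fold change -3.51, adjusted p = 0.00697). MYC, a growth regulator, had -0.71, MDM2, the ubiquitin ligase of p53, 0.38, and ALB, serum albumin, -1.15. In all, 6412 of 14235 genes changed (45.0%), 2948 higher and 3464 lower, of which 709 and 567 changed at least 2-fold. With library totals alone in place of TMM, 60.6% of the called genes were higher instead of 46.0%.

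**Figure D1:**
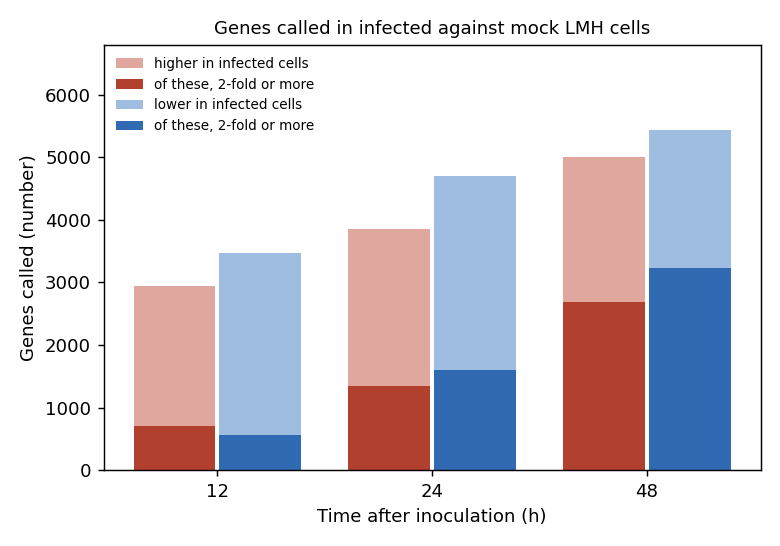
Number of genes higher and lower in infected than in mock cells at 12, 24 and 48 h (y axis, genes; x axis, time), with the part that changed at least 2-fold set apart in each bar. The number rises from 6412 genes at 12 h to 10450 at 48 h, out of 14235 tested.

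At 24 h, the question was which genes differed midway through the time course. The rise of the amino acid response and the fall of liver genes were larger in many members. SLC7A3, a carrier of cationic amino acids, rose from 81.3 ± 6.04 to 324 ± 23.1 CPM (SD, n = 3), a log2 fold change of 2.00 ± 0.082 (SE, adjusted p = 3.67e-14). HNF4A (ENSGALG00000004285, chromosome 20, 5564388 to 5578996), a master regulator of liver genes, fell from 257 ± 22.9 to 39.1 ± 3.29 CPM, a log2 fold change of -2.72 ± 0.096 (adjusted p = 6.53e-15). INSIG1, a sterol-sensing regulator of cholesterol synthesis, fell from 849 ± 13.3 to 246 ± 1.59 CPM, a log2 fold change of -1.79 ± 0.069 (adjusted p = 1.96e-14).

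Of 39 S phase genes, 35 rose and 1 fell, and 36 and 1 did adjusted over the list alone (median 0.69, adjusted p = 4.56e-12). E2F7, a repressor of the E2F family, rose by 2.38, GINS2 by 1.92 and TYMS by 1.48. Of 24 genes of the ATF4 and amino acid response, 19 rose and 1 fell, and 19 and 1 did adjusted over the list alone (median 1.13, adjusted p = 1.24e-10), with CHAC1 at 3.63 and ASNS at 1.98. Hepatocyte secreted proteins fell in 32 of 33 cases, and in 32 adjusted over the list alone (median -1.78, adjusted p = 1.34e-13), and liver transcription factors and metabolic enzymes in 24 of 26 with 1 rise, in both counts (median -1.63, adjusted p = 1.24e-08). RBP4, the retinol carrier of plasma, had a log2 fold change of -1.83 and G6PC -3.89. In mock cells the members of the secreted list had a median of 0.56 at 48 against 12 h, and those of the enzyme list 0.42. Interferon-stimulated genes fell in 15 of 18 cases with 0 rises, in both counts (median -0.46, adjusted p = 0.00215), with TRIM25 at -1.15, IFI35 at -0.95 and PARP12 at -0.82. These 5 lists kept their call with an estimated correlation.

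Of 19 genes of cholesterol synthesis, 13 fell and 0 rose, and 14 fell and 1 rose adjusted over the list alone (median -0.42, adjusted p = 0.00841; adjusted p = 0.184 with an estimated correlation). ACAT2, which condenses acetyl-CoA, had -1.48 and MSMO1, a sterol oxidase, -0.86. Of 20 genes of fatty acid and triglyceride synthesis, 13 fell and 2 rose, and 14 and 2 did adjusted over the list alone (median -0.47, adjusted p = 0.0181; adjusted p = 0.101 with an estimated correlation). ELOVL5, an elongase of polyunsaturated fatty acids, rose by 1.93, whereas AGPAT2, an acyltransferase, had -1.18 and PLIN2, a lipid droplet protein, -0.95. Ribosomal proteins fell in 56 of 66 cases with 1 rise, and in 57 with 1 rise adjusted over the list alone (median -0.49, adjusted p = 2.49e-07; adjusted p = 0.628 with an estimated correlation), with RPL37 at -1.20 and RPL34 at -1.04. Of 58 nuclear-encoded genes of oxidative phosphorylation, 35 fell and 4 rose in both counts, that adjusted over the list alone included (median -0.33, adjusted p = 0.00677; adjusted p = 0.748 with an estimated correlation), among them NDUFA4, COX7C and UQCRB at -1.09, -1.25 and -0.76. Without replicate 2 of mock cells at 24 h the adjusted p of this list was 0.0522. In mock cells, ribosomal proteins and genes of oxidative phosphorylation had medians of 0.34 and 0.30 at 48 against 12 h.

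By the rule that asks for more than 3 counts in the lower group, the largest rises at 24 h were those of OSTN, MEOX2, MMEL1, GGCL1 and NFASC, at 6.47, 5.60, 5.15, 4.98 and 4.85. MEOX2, a homeobox transcription factor of mesoderm, went from 0.168 ± 0.291 to 8.78 ± 0.402 CPM (adjusted p = 8.94e-10). Among the largest falls by that rule were those of FABP2, CLDN2, AGT and G6PC. FABP2, a fatty acid carrier, had -3.99 and AGT, the precursor of angiotensin, -3.94. MYC had -0.60, MDM2 0.60 and ALB -2.11. In all, 8556 genes changed (60.1%), 3857 higher and 4699 lower, of which 1350 and 1596 changed at least 2-fold. With library totals alone, 59.6% of the called genes were higher instead of 45.1%. Of the 2948 genes higher at 12 h, 2392 were also higher at 24 h (81.1%, against 799 under independence), and of the 3464 lower genes 2831 were also lower (81.7%, against 1143).

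At 48 h, the question was which genes differed at the end of the time course. Transcripts of the differentiated liver cell had fallen to low levels, and most S phase genes had risen further. G6PC (ENSGALG00000030034, chromosome 27, 5507166 to 5509834) fell from 559.7 ± 23.5 to 1.38 ± 0.833 CPM (SD, n = 3), a log2 fold change of -8.60 ± 0.19 (SE, adjusted p = 2.77e-19). HNF4A fell from 304 ± 6.77 to 3.78 ± 0.595 CPM, a log2 fold change of -6.33 ± 0.16 (adjusted p = 1.54e-18). TYMS rose from 88.4 ± 5.54 to 557 ± 16.8 CPM, a log2 fold change of 2.66 ± 0.064 (adjusted p = 1.16e-18). OSTN rose from 0.151 ± 0.111 to 114 ± 8.48 CPM, a log2 fold change of 9.46 ± 0.22 (adjusted p = 8.78e-19).

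All 33 hepatocyte secreted proteins fell, adjusted over the list alone as well (median -4.39, or -4.38 with genes at 0 counts set to their bound, adjusted p = 1.34e-13). RBP4 had a log2 fold change of -5.28, ITIH2, a hyaluronan-binding plasma protein, -5.84, F2, prothrombin, -3.28, and ALB -5.39. Of the liver transcription factors and metabolic enzymes, 24 of 26 fell and 1 rose in both counts, that adjusted over the list alone included (median -3.55, or -3.49 with bounds, adjusted p = 1.24e-08). CLDN2, CYP7A1 and cFuc-TIX had 0 counts in all 3 infected libraries, which put them at least 14.9-, 7.46- and 6.18-fold lower than in mock cells. Of 39 S phase genes, 33 rose and 1 fell in both counts, the list alone included (median 1.29, adjusted p = 5.76e-10), with DTL at 3.02 and E2F7 at 3.34. These 3 lists kept their call with an estimated correlation. Of 24 genes of the ATF4 and amino acid response, 17 rose and 5 fell, and 17 and 5 did adjusted over the list alone (median 0.87, adjusted p = 0.000825; adjusted p = 0.0749 with an estimated correlation). ATF3, a stress-induced transcription factor, rose by 3.67, SLC7A3 by 2.69, and PPP1R15B, a regulatory subunit of the phosphatase that acts on eIF2-alpha, by 2.07.

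**Figure D2:**
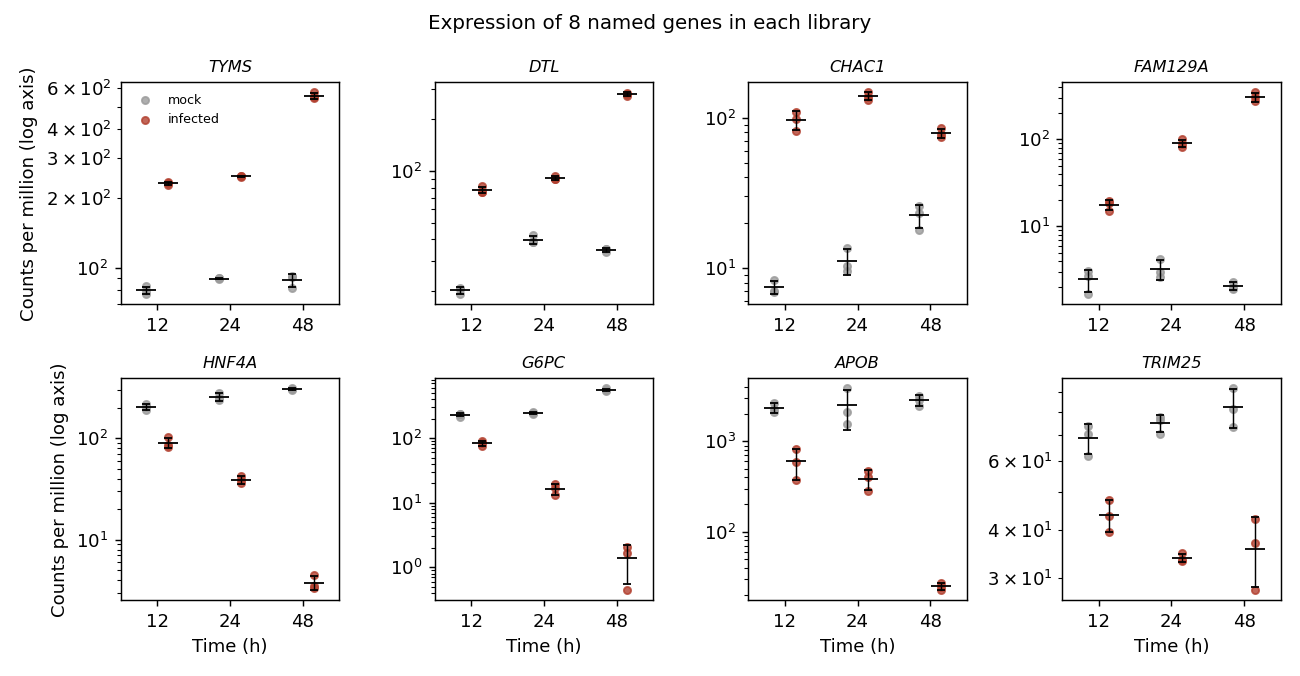
CPM in each library (y axis, log scale) of TYMS, DTL, CHAC1, FAM129A, HNF4A, G6PC, APOB and TRIM25 at 12, 24 and 48 h (x axis), for mock and infected cells, with the mean and SD over 3 replicates. HNF4A goes from 304 CPM in mock cells to 3.78 CPM in infected cells at 48 h, and TYMS from 88.4 to 557.

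Cholesterol synthesis genes fell in 16 of 19 cases with 1 rise, in both counts, the list alone included (median -1.21, adjusted p = 0.000458; adjusted p = 0.0915 with an estimated correlation). INSIG1 had -3.68 and LSS, the lanosterol synthase, -2.08. Of 20 genes of fatty acid and triglyceride synthesis, 15 fell and 3 rose in both counts, the list alone included (median -0.87, adjusted p = 0.0200; adjusted p = 0.103 with an estimated correlation). SREBF1, the transcription factor of lipid synthesis, had -2.07 and ACLY, which makes cytosolic acetyl-CoA, -1.85, whereas ELOVL5 rose by 3.06. Ribosomal proteins fell in 53 of 66 cases with 5 rises, and in 54 with 5 rises adjusted over the list alone (median -0.80, adjusted p = 6.04e-06; adjusted p = 0.725 with an estimated correlation), with RPL37, RPS25 and RPS6 at -2.33, -2.03 and -1.46. Nuclear-encoded genes of oxidative phosphorylation fell in 46 of 58 cases with 5 rises, in both counts, the list alone included (median -0.85, adjusted p = 7.96e-05; adjusted p = 0.544 with an estimated correlation), with ATP5J at -2.86, NDUFA4 at -2.55 and NDUFS1 at -1.33.

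Interferon-stimulated genes fell in 13 of 18 cases with 1 rise, in both counts, the list alone included (median -0.67, adjusted p = 0.0376; adjusted p = 0.0915 with an estimated correlation). IFI35 had -2.33, ZNFX1, a helicase with antiviral activity, -1.43 and TRIM25 -1.20, whereas CD47 rose by 0.38. The call of this list held in 2 of the 18 fits that left out 1 library, those without replicate 2 or replicate 3 of infected cells at 48 h. Without replicate 1 of infected cells at 48 h the adjusted p was 0.0785, and without any single library of the other 5 groups it lay between 0.0532 and 0.0638.

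With the same requirement of more than 3 counts in the lower group, the largest rises at 48 h after OSTN were those of GGCL1, FAM129A, NCF4 and SLCO5A1, at 9.25, 7.21, 6.66 and 6.06. FAM129A, a regulator of stress-induced translation, went from 2.07 ± 0.214 to 308 ± 36.3 CPM (adjusted p = 1.75e-18). Besides G6PC, the largest falls under this requirement included those of KNG1, TM4SF4 and PLPP3, at -7.99, -7.93 and -7.49. KNG1 encodes kininogen of plasma and PLPP3 a lipid phosphatase. MYC had -1.69 and MDM2 0.70. COX3, a mitochondrially encoded subunit of cytochrome oxidase, had 0, 0 and 1 count in the 3 infected libraries at 48 h against 12060 ± 809 CPM assigned to it in mock cells. Its adjusted p was 1.37e-06, but 0.435 with limma-voom, and other mitochondrial genes held the mitochondrial counts of those libraries. In all, 10450 genes changed (73.4%), 5010 higher and 5440 lower, of which 2690 and 3227 changed at least 2-fold and 265 and 311 at least 16-fold. Of the 3857 genes higher at 24 h, 3376 were also higher at 48 h (87.5%, against 1357 under independence), and of the 4699 lower genes 4044 were also lower (86.1%, against 1796).

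**Figure D3:**
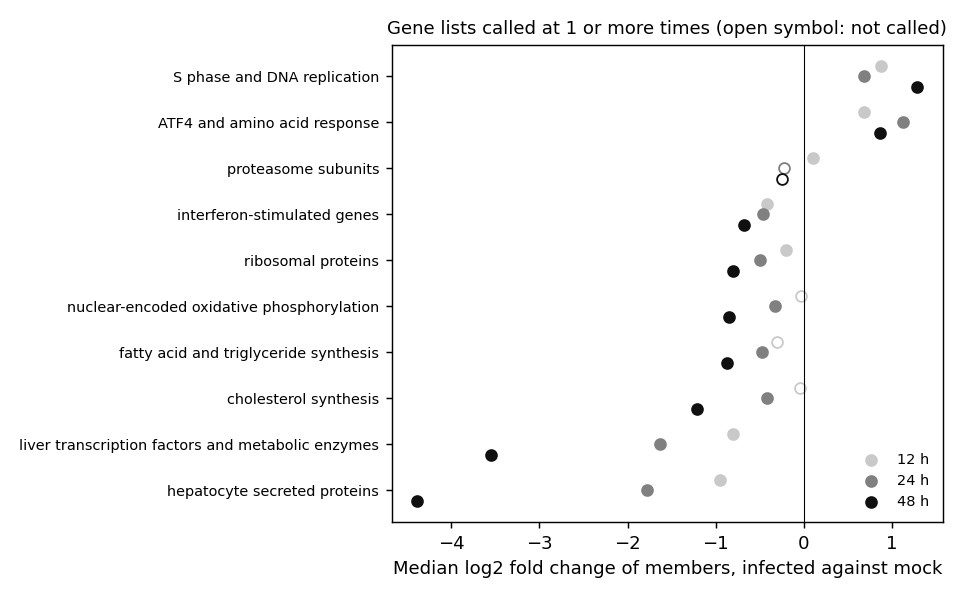
Median log2 fold change of the members (x axis) of 10 gene lists (y axis) between infected and mock cells. The shade of the symbol gives the time (12, 24 or 48 h), with an open symbol where the list was not called. The medians of hepatocyte secreted proteins go from -0.95 through -1.78 to -4.39, and those of S phase genes from 0.88 through 0.69 to 1.29.

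**Figure D4:**
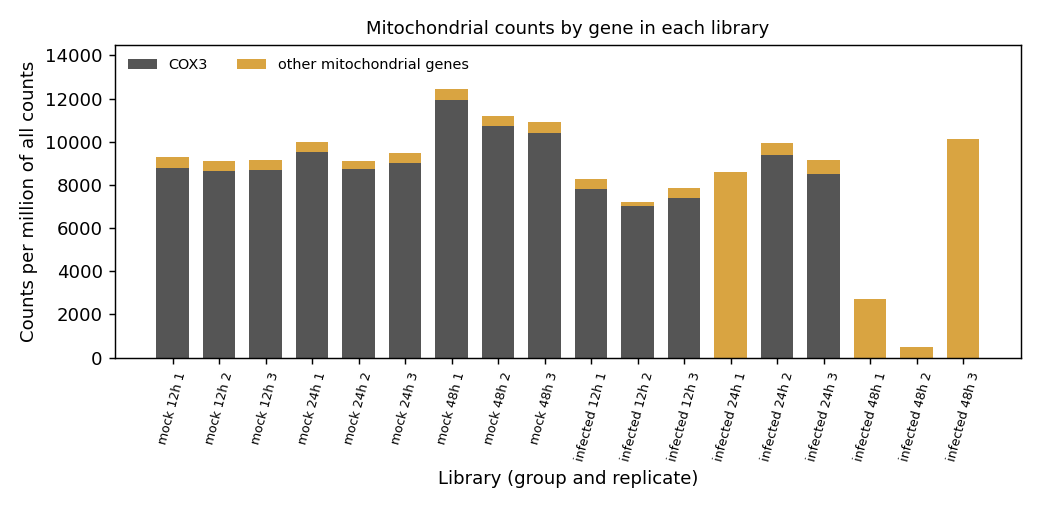
CPM on COX3 and on the other mitochondrial genes in each of the 18 libraries (y axis, CPM over the library total; x axis, library). COX3 holds most of the mitochondrial counts in mock cells and in infected cells at 12 h, and is absent in replicate 1 of infected cells at 24 h and in the 3 libraries at 48 h, apart from 1 count.

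Averaged over the 3 times, which asks for the mean infection effect over the time course, 11059 genes changed, 5167 higher and 5892 lower. A gene can pass this test through a change at some of the times only. At all 3 times, 2151 genes were higher and 2572 were lower, among them TYMS, GINS2, MTHFD2 and SLC7A3 on the higher side and HNF4A, G6PC, ALB and INSIG1 on the lower. A further 2302 genes were called at no time.

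The difference between times asks whether the infection effect itself changed. From 12 to 24 h, the infection effect became lower in 21 of 33 hepatocyte secreted proteins and higher in 0. It became lower in 15 of 26 liver transcription factors and metabolic enzymes and higher in 2. The effect is that of infected against mock cells, so a rise in mock cells also lowers it. AGT had a difference of -2.80 on the log2 scale (adjusted p = 0.000712) and ALB of -0.96 (adjusted p = 0.00745). In the ATF4 and amino acid list the effect became higher in 13 of 24 genes and lower in 1, and in cholesterol synthesis lower in 11 of 19 and higher in 0. In S phase genes it became lower in 11 of 39 and higher in 2. Overall 2810 genes differed, 943 toward higher and 1867 toward lower values. From 24 to 48 h, the effect became lower in 26 of 33 secreted proteins and higher in 0. Among all genes that met the naming rule, not this list alone, the largest differences toward lower values were those of KNG1, TM4SF4 and PLPP3. They had -5.59, -5.35 and -5.37 (adjusted p = 4.87e-11, 1.62e-14 and 1.93e-13). The infection effect became higher in 26 of 39 S phase genes and lower in 2. In the ATF4 and amino acid list it became lower in 12 of 24 genes and higher in 3. In mock cells 14 genes of this last list rose and 3 fell over the whole time course, with a median of 0.42 at 48 against 12 h. From 24 to 48 h, mean CHAC1 went from 139 to 78.9 CPM in infected cells and from 11.2 to 22.4 CPM in mock cells. In this interval 5620 genes differed, 2455 toward higher and 3165 toward lower values. These counts are over all genes tested, and the lists were not tested as sets for differences between times.

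The mock time course gives the background of culture without virus. Adjusted p-values in this paragraph are from the joint test of the 3 mock groups. A gene that passed it is counted as risen or fallen by its direction at 48 against 12 h. Liver genes rose in mock cells: of 33 hepatocyte secreted proteins 24 rose and 4 fell (median 0.56 at 48 against 12 h), and of 26 liver transcription factors and metabolic enzymes 16 rose and 3 fell (median 0.42). ALB rose from 28.9 ± 1.72 CPM at 12 h to 158 ± 13.8 CPM at 48 h (SD, n = 3), a log2 fold change of 2.46 (adjusted p = 2.65e-10). AGT rose by 3.05 (adjusted p = 3.32e-09), CYP7A1, the rate-limiting enzyme of bile acid synthesis, by 3.55 (6.53e-06) and PACAP, a neuropeptide precursor, by 3.65 (4.61e-05). SLC26A3, an anion exchanger, had -4.40 (3.32e-09), ACE, the angiotensin-converting enzyme, -4.19 (7.18e-10) and HKDC1, a hexokinase, -4.01 (3.03e-05). Extracellular matrix and adhesion genes fell in 19 of 41 cases with 1 rise. In all, 4131 genes changed, 2281 toward higher and 1850 toward lower values at 48 than at 12 h. With library totals alone 40.7% of them were higher, and with scaling on reference genes 66.4%, against 55.2% with TMM.

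Among 117 KEGG pathways, 26 were shifted at 12 h, 28 at 24 h and 28 at 48 h. At 12 h, ribosome biogenesis rose in 31 of 45 genes and fell in 1 (median 0.33, adjusted p = 2.04e-07), and DNA replication rose in 16 of 20 genes and fell in 0 (median 0.51, adjusted p = 6.51e-07). With an estimated correlation these 2 pathways kept their call at 12 h (adjusted p = 0.0345 and 0.0262) and no other KEGG pathway did at any time, with 28, 21 and 20 pathways at an unadjusted p under 0.05. At 48 h, genes of the citrate cycle fell in 15 of 17 cases (median -0.98, adjusted p = 0.000758; adjusted p = 0.171 with an estimated correlation) and genes of xenobiotic metabolism by cytochrome P450 in 18 of 22 with 2 rises (median -2.11, adjusted p = 0.000653; adjusted p = 0.171 with an estimated correlation). Genes of mRNA surveillance rose in 35 of 50 cases with 7 falls (median 0.47, adjusted p = 0.00118; adjusted p = 0.0990 with an estimated correlation). Among 2639 GO terms, 81, 54 and 37 were shifted at 12, 24 and 48 h; with an estimated correlation in camera, 0, 0 and 0 were, with 527, 271 and 210 at an unadjusted p under 0.05.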

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

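The tests of the rise of liver genes in mock cells, of the scaling of the liver genes, of the locus lengths of silent genes, of their neighbours among genes with a measured distance, and of the mitochondrial counts were chosen only after the result was seen. The infection effect differed between time points by a test of the difference itself in 2810 genes from 12 to 24 h and in 5620 from 24 to 48 h, and in 66 and 83 of the 106 genes named for infection. From 12 to 24 h the largest differences among genes that met the naming rule were 5.15 for H2A-VI (adjusted p = 0.000271), 4.82 for GGCL1 (1.53e-05) and 3.79 for SP9 (0.0326) toward higher values, and -3.65 for TNFAIP6 (0.0229), -2.80 for AGT (0.000712) and -2.57 for CLDN2 (0.0105) toward lower ones; ALB had -0.96 (0.00745). H2A-VI overlaps an unnamed histone-like gene model, ENSGALG00000030658, whose counts split within a group, so that its value is uncertain. SP9 lost its call without replicate 1 (adjusted p = 0.0537) or 3 (0.0634) of mock cells at 12 h, without replicate 1, 2 or 3 of infected cells at 12 h (0.0814, 0.0653 and 0.0560), without replicate 1, 2 or 3 of infected cells at 24 h (0.0639, 0.0506 and 0.0613), and with scaling on reference genes (0.0529). TNFAIP6 lost it without replicate 1 of mock cells at 12 h (0.0640), replicate 3 of mock cells at 24 h (0.134), replicate 3 of infected cells at 24 h (0.0632), and replicate 1 of infected cells at 24 h (0.05 after rounding), and DESeq2 gave it no adjusted p. CLDN2 lost it without replicate 2 of infected cells at 24 h (0.0504).

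From 24 to 48 h the largest differences by that rule were 4.27 for GGCL1 (0.000108), 4.26 for GDPD4 (0.000868) and 4.17 for CAMK2A (0.00333) toward higher values, and -5.59 for KNG1 (4.87e-11), -5.37 for PLPP3 (1.93e-13) and -5.35 for TM4SF4 (1.62e-14) toward lower ones. Of the genes named at every time, ALB had -3.28 (1.63e-07) and MYC -1.10 (3.52e-06). CAMK2A lost its call without replicate 3 of mock cells at 24 h (adjusted p = 0.0797).

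Other splits of the libraries were used to ask whether they call as many genes as the real one. The 3 libraries against 3 at a single time allow 10 splits, too few for a share under 0.05. The real split called 6412, 8556 and 10450 genes at 12, 24 and 48 h, and the highest other split called 0 each time; 1 of 10 splits reached the real count in each case. For the 4 results with 100 splits, 1 split, the real one, reached the real count, a share under 0.05. The average over times had 11059 genes against 10130 at most in another split, and mock cells 4131 against 3121. The differences between times had 2810 against 2281 and 5620 against 5413. For these differences the splits exchanged time labels within infected and within mock cells. They therefore ask whether time matters in either arm, and cannot tell whether the infection effect itself changed.

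The fall of hepatocyte secreted proteins and liver enzymes was weighed against 3 technical explanations, and each was argued against within the limits given here. The 59 members lay at a median log2 difference of -3.37 between infected cells at 48 h and mock cells at 12 h, so that a rise in mock cells over time does not account for the fall. Among 10000 random lists matched on abundance and length, the lowest median at 48 h was -0.81 against -3.89 observed. Abundance here is the mean over all 18 libraries, the infected ones included, so the lists were not matched on abundance in mock cells alone. Over 5 scalings the median ran from -3.89 to -3.65, so that the choice among these 5 does not account for the fall. A scaling moves all genes of a library by a common factor, so a fall this large could hardly have been lost. All 5 rest on host counts, and none can show a change in the total host mRNA of a cell. A loss of liver cell transcripts in infected cells is a candidate explanation, as a hypothesis found and tested on the same data, and its basis was not tested.

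Genes silent in mock cells gained counts: of 8390 silent nuclear genes, 162 reached 1 CPM over the pooled infected libraries at 48 h with counts in all 3. Of the 162, 88 were called higher at 48 h by the gene test. An even background spread over whole loci, introns included, as the whole cause was argued against. The 162 genes had a median locus length of 7.93 kb. Genes passing the same rule in 1000 simulated even spreads had medians of at least 171 kb. These simulations cannot decide on a background spread by transcript length. Yet the top 1% of silent genes held 42.0% of the counts against 33.0% under an even spread. The planned test takes this as fitting an even background. The other 8228 silent genes together went from 113 CPM in mock cells to 507 CPM in infected cells at 48 h. A version by transcript length, added afterwards, is void because 51.4% of silent genes have a length. Whether reads running over from active neighbours contribute cannot be told apart: 29.6% of these genes against 17.1% of other silent genes lay within 10 kb of an active gene (permutation p = 7e-05, 100000 permutations), but 4016 of the other 8228 lay on sequences without any active gene, and among genes with a measured distance the shares were 32.7% and 33.3% (permutation p = 0.601 for a larger share), with 49 of 147 beyond 50 kb. No biological explanation was tested.

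COX3 was at or near 0 in replicate 1 of infected cells at 24 h and in all 3 at 48 h. At 24 h, assignment of mitochondrial reads to another gene may account for it: MT-CYB led in that library, and its mitochondrial CPM were 0.942 of the lower of the other 2. At 48 h this cannot be told apart from a loss of COX3, because the libraries differ: they held 2718, 497 and 10130 CPM, 0.879 of the mock mean at most, each led by another gene. Without replicate 1 of infected cells at 24 h, COX3 at 12 and 24 h had adjusted p = 0.00118 and 0.0488. In mock libraries COX3 held 94.7% to 96.1% of the mitochondrial counts, and 11 or 12 of 37 mitochondrial genes had any counts. Whether the counts given to COX3 in mock cells all come from its own transcript was not tested. No biological explanation was tested.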

How the results depend on the processing

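The alternative without genes whose counts split within a group was chosen after the mitochondrial counts had been seen; all others were fixed beforehand. The counts of genes kept within 1.5 times of their values in all alternatives but 1: for changes beyond 1.5-fold, 1353, 3496 and 6800 genes passed at 12, 24 and 48 h, 4857 averaged over times, and 260 and 1844 for the differences between 12 and 24 h and between 24 and 48 h, which follows from the stricter hypothesis. That test was not run for the mock time course, which has 2 contrasts; the fit of the compared groups alone gives no separate value for the average over times; and the alternatives for FPKM alone were not needed, since counts were used. With 1 of 18 libraries left out, the counts ranged over 5555 to 6685 at 12 h, 7868 to 8891 at 24 h, 9838 to 10696 at 48 h, 10844 to 11215 averaged, 2009 to 3270 and 5044 to 5869 for the differences between times, and 3089 to 4504 in mock cells, and the lists called over 6 to 9, 9 to 10 and 8 to 9.

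With an estimated correlation, 5 lists were called at 12 h, 5 at 24 h and 3 at 48 h, in place of 7, 9 and 9; 2, 0 and 0 KEGG pathways were, and 0, 0 and 0 GO terms. With fry, 16, 17 and 23 lists were called; at 48 h it gave the opposite direction to camera for p53 targets (adjusted p = 0.000788), mitosis (0.000613), heat shock proteins (8.73e-05) and glycolysis and hypoxia response (0.00550), 4 lists not called by camera. Camera ranks a list against other genes and fry does not. Replicate numbers were not taken to pair the libraries: infected and mock libraries with the same number had a median correlation of 0.0211 (-0.0655 to 0.107, 2 of 9 pairs over 0.1), against 0.00404 (-0.305 to 0.296) for different numbers in any 2 groups, and 9 of 18 libraries correlated best with their own number. With a replicate block the counts were 6286, 8502 and 10385 at the 3 times, 11003 averaged, 2593 and 5474 for the differences and 3903 in mock cells, and 7, 9 and 9 lists.

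Scaling moved the balance of directions. The median log2 fold change of all genes was -0.0351, -0.0615 and -0.0542 at the 3 times with TMM and 0.0694, 0.123 and 0.191 with library totals alone, and the share of called genes that were higher at 48 h went from 47.9% to 57.6%. For the difference between 12 and 24 h it went from 33.6% to 47.0%, and without a filter that between 24 and 48 h went from 43.7% to 32.3%. No list that was called at a time changed the sign of its median at that time under any of the 5 scalings. Of the genes called at the 3 times, DESeq2 also called 96.3%, 94.8% and 96.5%, and limma-voom 99.1%, 98.9% and 97.7%. Without genes split within a group, 6413, 8557 and 10446 were called. For named genes, 5619 comparisons kept their direction and side of the threshold, 57 lost the call, 27 of them in the test beyond 1.5-fold, and 13 gained it. Depth limits what can be shown for genes with few counts: 3 counts are 0.210 to 0.332 CPM in mock and 12 h infected libraries and 1.08 to 1.42 CPM in infected libraries at 48 h.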

Other observations

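The tests in this part were chosen before the result they measure was seen, except that the genes DDX4, SLA, KCNQ3 and ALDH1A1 were picked after their values were seen. Extracellular matrix and adhesion genes did not pass the list test at 48 h (list adjusted p = 0.111; adjusted p = 0.187 with an estimated correlation): 23 of 41 rose and 11 fell, or 25 and 11 adjusted over the list alone, with a median of 0.80. In mock cells 19 of them fell and 1 rose, with a median of -0.48 at 48 against 12 h. LAMA1, a laminin chain of the basement membrane, rose by 2.09, 3.04 and 4.79 on the log2 scale at 12, 24 and 48 h. Of 35 genes of the transcription and splicing machinery, 18 rose and 5 fell at 48 h in both counts (median 0.31, list adjusted p = 0.0669). At 24 h, where 17 rose and 5 fell (median 0.26), the list's adjusted p was 0.0560, against 0.182 with an estimated correlation, 0.0369 with DESeq2 size factors, 0.0152 with library totals alone, 0.0205 without a filter and 1.91e-05 with fry, and 14 of 18 fits that left out a library called it, the lowest at 0.0214 without replicate 2 of infected cells at 24 h. It stayed uncalled without replicate 3 of mock cells at 12 h, replicate 2 or 3 of infected cells at 12 h, or replicate 1 of infected cells at 24 h, the last with the highest value (0.107). MED17, a Mediator subunit, rose by 1.56 at 48 h, and SF3B1, a splicing factor, had -1.39.

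The other lists not called at any time held genes that moved in both directions at 48 h, in the same numbers adjusted over the list alone. In the sensing of viral RNA and DNA, 6 of 15 rose and 5 fell (median -0.14, mean 0.21, list adjusted p = 0.827; the sign of the median differs with upper quartile scaling and with library totals alone), with TRAF6, an adaptor of Toll-like receptors, at 1.44. NF-kB and inflammatory cytokine genes rose in 10 of 23 cases and fell in 10 (median 0.07, mean -0.47, 0.827), with TNFSF15 at -3.20. MAPK and immediate early genes rose in 10 and fell in 16 of 31 (median -0.31, 0.850); DUSP4, a phosphatase of MAP kinases, had risen by 1.60 at 12 h. Of 20 p53 targets, 9 rose and 8 fell (median 0.25, mean -0.01, 0.850), with BTG1, an antiproliferative gene, at -3.16. Of 31 mitosis genes, 12 rose and 12 fell (median -0.06, 0.976), with CDC20, an activator of the anaphase-promoting complex, at -2.46; camera gave the direction of this list as up, against the sign of its median, which differs under all 4 other scalings. ER chaperones and the unfolded protein response had 10 rises and 9 falls in 25 genes (median 0.05, mean -0.09, 0.976), with DNAJB9 at 1.95. Heat shock proteins had 7 and 8 in 19 (median 0.09, mean -0.04, 0.976), with HSPA2 at -1.68.

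Autophagy genes rose in 10 and fell in 15 of 34 cases at 48 h (median -0.05, list adjusted p = 0.727), with LAMP1, a lysosomal membrane protein, at -1.89; the sign of this median differs under all 4 other scalings. Apoptosis genes rose in 7 and fell in 13 of 25 (median -0.27, 0.505), with TNFSF10, the death ligand TRAIL, at -4.10. Genes of glycolysis and the hypoxia response rose in 10 and fell in 7 of 23 (median 0.15, mean -0.22, 0.770), with PFKFB3, a regulator of glycolysis, at -3.31. Factors of adenovirus entry, transport and nuclear export rose in 11 and fell in 8 of 22 (median 0.09, 0.749), with IPO7, an importin, at 1.62. Histones rose in 3 and fell in 4 of 10 (median -0.46, 0.973), with HIST1H4A at 3.20. Reference genes rose in 7 and fell in 9 of 22 (median -0.12, 0.973; the sign differs with upper quartile scaling and with library totals alone), with ALAS1, an enzyme of heme synthesis, at -1.96. Markers of other lineages rose in 4 and fell in 4 of 17 (median 0.01, mean -0.42, 0.948), with CTSS, a cathepsin, at -3.06. Proteasome subunits at 48 h rose in 3 and fell in 14 of 26 (median -0.25, 0.0984).

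Among the silent genes that gained counts were SLA, KCNQ3 and DDX4, a germ cell helicase, at 29.1, 18.5 and 16.9 CPM in infected cells at 48 h, from 9, 8 and 10 counts summed over the mock libraries. Silent genes at 1 CPM or more over the pooled libraries, without the requirement of counts in all 3, numbered 14, 45 and 179 in infected cells at 12, 24 and 48 h; 162 of the last met that requirement. The other 8228 silent genes together went from 113 to 507 CPM at 48 h.

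The share of counts on chromosome Z was 3.38 ± 0.057% in mock cells at 48 h and 2.16 ± 0.056% in infected cells (SD, n = 3). A lower expression along the chromosome was tested as a hypothesis and was argued against: the median log2 change of 617 Z genes was -0.0466 relative to genes on numbered chromosomes (permutation p = 0.470, 10000 permutations). ALDH1A1, a retinal dehydrogenase, made up 47.5% of the net loss.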
